A study of Mus musculus with 12 samples.

How the data were processed

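Total RNA from mouse ileum was counted on the nCounter Mouse Tumor Signaling 360 panel, which holds probes for 760 tumour-related and 20 housekeeping genes, per the labels' protocols. The 12 libraries come from 3 mice in each of 4 groups, and the 3 were drawn at random from the 8 mice of a group, per the series description. RNA was extracted with a MasterPure kit and samples with an RNA integrity number above 7.0 were kept, per the labels' protocols. Mice received DMSO or STP1002 by mouth once daily, or G007-LK by intraperitoneal injection 2 times a day, for 28 days, per the labels' treatment protocol. Strain, sex and age are not given.

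The deposited table has 794 features: 780 genes, 8 negative control probes and 6 positive control probes. The unit of the gene values is a normalized signal, deposited by the authors on a linear scale. In each library the deposited gene values are a whole count of reporters times 1 factor, as found from the values themselves, with nothing below a floor of 1. A single step per library returned whole counts within a tolerance of 0.0051 for 98.7% of genes in G007-LK replicate 1, 99.2% in G007-LK replicate 3, 99.4% in control replicate 1 and 100% in the other 9 libraries. The genes that gave no whole count lie at the floor. The control probes are whole counts and were not scaled. The software, the background rule and the reference genes of the authors' normalization are not stated in the labels. The table does not mark housekeeping genes. A search of the values found 20 genes whose geometric mean is nearly constant over the libraries (72.4873 to 72.4947), with an SD of the log geometric mean of 2.79e-05 against 0.0745 as the smallest of 10000 random sets of 20 genes. These 20 are called the reference genes, and they were inferred, not read from a label. The factor that remains after the positive controls differs by 14.4-fold between libraries.

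The background threshold of a library was the mean plus 2 SD of its negative control counts, put on the deposited scale with the library's factor. It averaged 23.1 and ranged from 4.33 to 40.4, and 0 to 7 of the 20 reference genes lay at or below it in a library. Recovered counts summed to between 31901 and 508829 per library, with a median of 24 counts per gene in control replicate 3 and 138.5 in G007-LK replicate 1. Genes near the floor of the shallow libraries therefore rest on few counts. Symbols were matched to a RefSeq gene table of the mouse for names only: 775 matched by symbol, 2 by synonym, and 3 probes that cover several genes did not match. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between pairs of replicates from 3.21 to 129.2.

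The choice of tests, comparisons, gene lists and named genes was made before the data were examined, and it provided for raw counts, linear normalized values or log2 values. As the values are linear and normalized, limma was applied to log2(value + 1) of all 780 genes, with lmFit on a cell-means design of the 4 groups over all 12 libraries and eBayes with a mean-variance trend (prior degrees of freedom 8.76, total 16.8). No gene was filtered out. Tests were two-sided, with Benjamini-Hochberg adjustment over the 780 genes of a comparison, and a gene was called at an adjusted p under 0.05. Each treatment was compared with control, both STP1002 doses together with control, and the treatments with one another. A moderated F test asked for any difference among the 4 groups. Group means are arithmetic means of the deposited signal with SD, while fold changes are differences of mean log2 values with the moderated SE. For a gene at or below background in all libraries of 1 group, the fold was computed against the background threshold of that group and is given as a lower bound.

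Of 36 fixed gene lists, 26 had at least 4 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Camera sets a list against the other genes of a panel that was itself chosen for tumour signalling. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list was called in any comparison. Calls "adjusted over the list alone" apply the Benjamini-Hochberg step to the members of 1 list. The members of the lists were not selected on these samples.

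Named genes follow a fixed rule. Against control these are up to 10 rises and 10 falls with the largest log2 fold change among called genes whose groups do not overlap, and 5 and 5 between treatments. With fewer than 5 such genes, the 5 genes with the smallest p are given as not called. The 17 core genes of the Wnt pathway and crypt are named in each comparison with control where measured (5 were), as are 2 to 4 members with the smallest p of each called list or list with at least 3 called members. Genes with a mean below the mean background of 23.1 are named as low, without values. Genes named outside the rule are marked as such where they appear.

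The labels number the mice of each group without stating that equal numbers pair mice. Residual correlations between equally numbered libraries, each against its group, were computed before calls were compared. They ran from 0.307 to 0.600 between control and G007-LK, from 0.159 to 0.776 between control and STP1002 at 10 mg/kg, and from 0.144 to 0.559 between the latter and G007-LK, all above the limit of 0.1. Replicate 3 nevertheless correlated better with another number than with its own in each of these 3 pairs of groups (0.429 against 0.307, 0.567 against 0.159 and 0.248 against 0.144), so that the pairing is uncertain for it. The pairs of STP1002 at 5 mg/kg did not pass it, with ranges of 0.0276 to 0.364 with control, 0.0112 to 0.314 with G007-LK and 0.0176 to 0.463 with 10 mg/kg. The unpaired fit was kept as planned, and values with the replicate number as a block are given beside it.

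The tests were tried on simulated counts drawn from the means and depths of the real genes, with 50 genes at each of 4 fold sizes changed in G007-LK. In the simulated comparison of G007-LK with control, limma over 780 genes recovered 6% of changes of 2-fold, 56% of 4-fold, 84% of 8-fold and 96% of 16-fold, and called 2 of 580 unchanged genes. Recovery was 8%, 70%, 96% and 100% for edgeR, and 10%, 76%, 94% and 98% for DESeq2, which called 7 of 580 unchanged genes. In the simulated STP1002 comparisons without change, the 3 tools called 0 of 780 genes. A list raised by 2-fold in all its 22 members was called and 0 of 25 others were. The simulated genes were drawn independently of one another, so this does not show how often camera calls lists of correlated genes. In the real libraries, other splits of the G007-LK and control mice called a median of 3 lists and at most 6. Differences of 2-fold in single genes were thus mostly out of reach with 3 mice per group, and those of 8-fold mostly within it.

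Whether both compounds move the same genes was measured as the covariance across genes of their log2 fold changes, set against simulated unchanged groups that share the control libraries. The simulation was repeated with gene-to-gene correlation and with the residual spread of a fit with the replicate block over control, STP1002 at 10 mg/kg and G007-LK, all of which was added later.

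Alternatives planned at the outset were a pseudocount of 10 or none, leaving out genes with a mean under 20 or under 100, rescaling by median ratios, rescaling on the 15 measured genes of a fixed reference list, quantile normalization, eBayes without trend or robust, array weights, fits of the compared groups alone, the replicate block, an adjusted p under 0.1, the other list tests, and leaving out each mouse in turn. Added after the values had been seen were edgeR's quasi-likelihood test with TMM factors and with none and DESeq2, all on the recovered counts, and subtraction of the mean negative control. The others added then were a common background floor of 40.4, a restriction to 625 genes above background in at least 9 libraries, omission of the 2 deepest libraries or of the 3 outermost on the first principal component, and rescaling on the 12 reference genes above background in all libraries. Calls were also counted for other divisions of the same libraries into groups of equal size, all 10 for 3 against 3 and 100 random draws elsewhere; draws within the replicate numbers were added later for the test of any difference. Control probes were left out of the tests and depths. Some measured genes are not reported here. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.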

Results

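Expression of 780 genes of a targeted tumour signalling panel was counted in the ileum of 12 mice. Each of 4 groups contributed 3 mice, picked at random from the 8 that had been assigned to the group. Control mice received DMSO by mouth once daily for 28 days. STP1002 was given by mouth once daily at 5 or at 10 mg/kg. G007-LK was injected into the peritoneum 2 times a day at 30 mg/kg. Both compounds are inhibitors of tankyrases, enzymes that act on axin in the Wnt pathway. Dose, route and schedule differ along with the compound, and the mice that received injections have no injected control.

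The libraries differed widely in depth. Summed gene counts were 293538, 43922 and 31901 in control replicates 1 to 3. They were 67398, 62239 and 44180 with STP1002 at 5 mg/kg, and 93017, 96703 and 54392 at 10 mg/kg. G007-LK replicates 1 to 3 held 508829, 50249 and 148454. The deepest library exceeded the shallowest by 15.95-fold, whereas the geometric mean of the spiked positive controls differed by at most 2.01-fold. Background from the negative control probes, on the deposited scale, ranged from 4.33 in control replicate 1 to 40.4 in G007-LK replicate 2. Above it in all 12 libraries were 539 of the 780 genes, and 16 were above it in none. A value above it does not by itself show expression, since 5 of 14 genes of other organs, the germ line and pluripotent cells, a list partly drawn up after values were seen, were also above it in all 12 libraries. The first principal component held 58.0% of the variance, with G007-LK replicate 1 at -49.6 and control replicate 1 at -26.1, and STP1002 10 mg/kg replicate 2 at 33.1 on the other side.

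**Figure D1:**
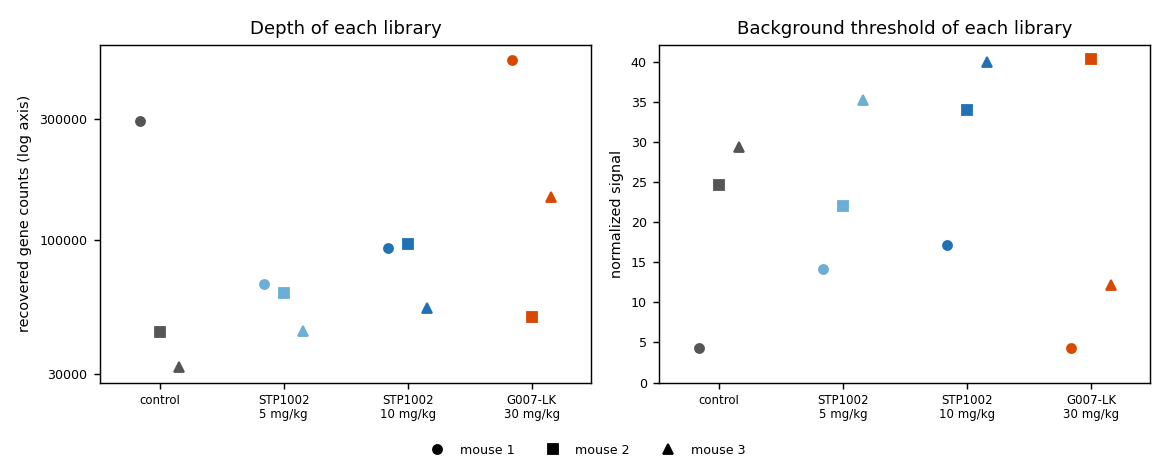
Depth and background of the 12 libraries, 3 mice per group. One panel plots the summed gene counts (log axis) and the other the background level in normalized signal, the mean plus 2 SD of the negative control probes; G007-LK replicate 1 has 508829 counts and control replicate 3 has 31901.

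Transcripts of 4 genes typical of macrophages and other myeloid cells were higher in the ileum after G007-LK than after DMSO. Gpnmb, a glycoprotein of macrophages, had a mean normalized signal of 12.6 ± 5.95 (SD, n = 3) in control mice and 1109 ± 810.0 (SD, n = 3) after G007-LK. Its log2 fold change was 6.17 ± 0.70 (SE), with an adjusted p of 9.14e-05 by limma. The lysosomal macrophage protein Cd68 rose from 88.8 ± 42.6 to 1074 ± 735.7 (log2 fold change 3.51 ± 0.56 SE, limma adjusted p = 0.00178). Cd14, a co-receptor for bacterial lipopolysaccharide, rose from 45.5 ± 25.7 to 703.7 ± 479.8 (log2 fold change 3.86 ± 0.73 SE, limma adjusted p = 0.00617). Tyrobp, a signalling adaptor of myeloid receptors, rose from 365.4 ± 81.3 to 2515 ± 1078 (log2 fold change 2.72 ± 0.44 SE, limma adjusted p = 0.00178). Each of these 4 genes was higher in 3 of 3 treated mice than in any control mouse.

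Other genes rose with G007-LK as well. Among them were Ms4a4a (log2 fold change 4.42 ± 0.81 SE), the integrin subunit Itgb2 (3.89 ± 0.83), the receptor Cd84 (4.56 ± 1.14), the exchange factor Vav1 (3.54 ± 0.75) and the NADPH oxidase subunit Cybb (3.57 ± 0.93). Their limma adjusted p values lay between 0.00565 for Ms4a4a and 0.0446 for Cybb, and Cybb was above background in 2 of 3 treated libraries. In control mice Gpnmb, these 5 genes and Cd44 were above background in 1 of 3 libraries. The secreted protease inhibitor Slpi rose by a log2 fold change of 3.77 ± 0.74 SE, and Lcn2, which binds bacterial siderophores, by 3.00 ± 0.71. Limma adjusted p was 0.00766 for Slpi and 0.024 for Lcn2. Thbs1, a matrix glycoprotein that activates TGF-beta, rose from 100.8 ± 12.9 to 1379.6 ± 1309 (log2 fold change 3.28 ± 0.61 SE, limma adjusted p = 0.00565). The basement membrane collagen Col4a1 rose from 463.0 ± 249.4 to 1666 ± 504.0 (log2 fold change 2.01 ± 0.53 SE, limma adjusted p = 0.0459). Cd44, a hyaluronan receptor and Wnt target, rose by a log2 fold change of 3.56 ± 0.91 SE (limma adjusted p = 0.0397).

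Limma called 9 genes lower with G007-LK. Ccnd1, the cyclin of G1 phase, fell from 910.1 ± 688.7 to 43.2 ± 24.1 (log2 fold change -4.32 ± 0.66 SE, limma adjusted p = 0.00138). Car9, a carbonic anhydrase induced by hypoxia, fell from 655.2 ± 173.0 to 34.9 ± 30.4 (log2 fold change -4.48 ± 0.63 SE, limma adjusted p = 0.0008). Sfn, the epithelial 14-3-3 sigma protein, had a log2 fold change of -3.37 ± 0.77 SE. The values were -3.04 ± 0.62 for the receptor tyrosine kinase Erbb3, -2.94 ± 0.64 for the epithelial protease inhibitor Spint2 and -2.25 ± 0.57 for Bad, which promotes apoptosis. Limma adjusted p for these 4 genes ranged from 0.0104 for Erbb3 to 0.0362 for Bad. The kinetochore gene Nuf2 was above background in 0 of 3 treated libraries and was at least 4.39-fold lower (limma adjusted p = 0.0109). Chek2 and Galnt3 were also called lower, at low signal.

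**Figure D2:**
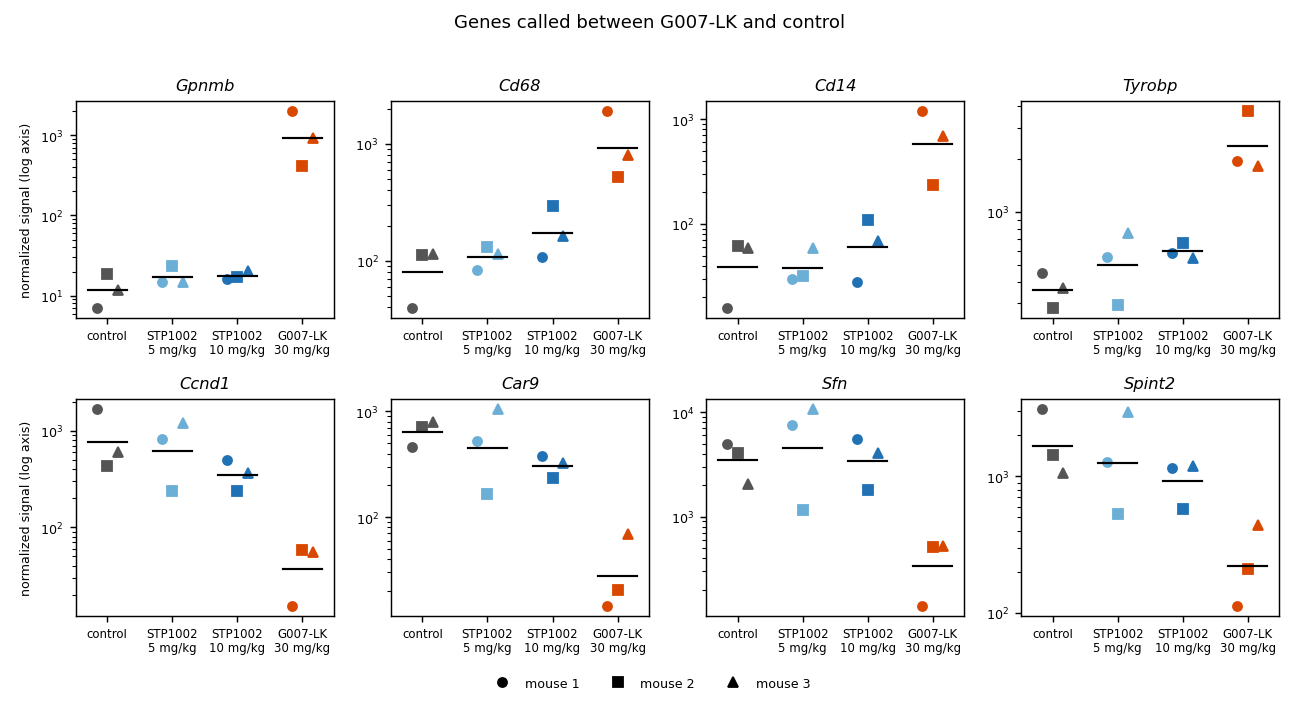
Normalized signal (log axis) of genes called by limma between G007-LK and control in all 4 groups, 1 point per mouse (n = 3 per group) and lines at the back-transformed group means of the log2 values. Gpnmb has a mean of 1109 after G007-LK and 12.6 in control mice, and Ccnd1 of 43.2 and 910.1.

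In total, limma called 27 of 780 genes between G007-LK and control at an adjusted p under 0.05, 18 higher and 9 lower. In all 27 the 3 treated mice lay beyond the 3 control mice; this held for 141 genes (18.1%) of the panel, where chance gives 10%. The unadjusted p was under 0.05 for 103 genes. The median log2 fold change of all genes was -0.09, and -0.36 after rescaling on the fixed reference list. Of the 17 core genes of the Wnt pathway and intestinal crypt, 5 were on the panel, and Axin2, Lgr5 and the tankyrases themselves were not analysed here. Apart from Ccnd1 and Cd44, the core genes did not pass the test. Beta-catenin (Ctnnb1) had a log2 fold change of 0.16 ± 0.49 SE, Myc of 0.27 ± 0.47 and the proliferation marker Mki67 of -0.02 ± 0.89. The sign turned with the scaling for each of the 3: Ctnnb1 (-0.11) and Myc turned negative after rescaling on the fixed reference list, and Mki67 had 0.02 after median-ratio rescaling. Limma adjusted p was 0.946, 0.885 and 0.992 for these genes. Other alternatives, given below, moved Mki67 further from 0 in both directions.

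Of 26 gene lists tested with limma's camera, 5 were called between G007-LK and control. Myeloid markers were higher (camera adjusted p = 6.3e-05; adjusted p = 0.833 with an estimated correlation). Of 22 measured members 18 were higher, the median log2 fold change was 0.89, and 5 rose: Cd68, Tyrobp, Cd14, Cd84 and Cybb. Adjusted over the list alone, 7 members rose and 1 fell. Inflammatory cytokines and NF-kB targets were higher in 14 of 17 members, with a median of 1.05 (camera adjusted p = 0.000447; adjusted p = 0.833 with an estimated correlation). Lcn2 rose, and 4 members did adjusted over the list alone. The cytokine Il6 had 3.10 ± 1.05 SE, the NF-kB inhibitor Tnfaip3 2.68 ± 0.78 and the adhesion molecule Icam1 2.503 ± 0.84, none of them called. Il6 had 9961 recovered counts in G007-LK replicate 1, the deepest library, and 53 and 176 in replicates 2 and 3. The median of the inflammatory list, centred over the 12 libraries, was 1.61, 0.06 and 0.18 in G007-LK replicates 1 to 3. In control replicates 1 to 3 it was -1.75, -0.35 and 0.03. Without G007-LK replicate 1 this list was not called.

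Fibroblast and matrix genes were higher in 14 of 17 members, with a median of 0.65 (camera adjusted p = 0.0054; adjusted p = 0.833 with an estimated correlation). Col4a1 rose, 2 members did adjusted over the list alone, and the microfibril gene Fbn1 (1.42 ± 0.44 SE), the proteoglycan Dcn (1.45 ± 0.55) and the receptor Pdgfra (1.13 ± 0.43) were not called. TGF-beta and BMP genes were higher in 10 of 13 members, with a median of 0.97 (camera adjusted p = 0.0121; adjusted p = 0.314 with an estimated correlation). Thbs1 rose, as the 1 member called adjusted over the list alone; the ligand Tgfb1 (2.03 ± 0.76 SE) and the receptor Tgfbr2 (1.13 ± 0.52) did not pass. Cell cycle genes were lower in the camera test, with 5 of 45 members higher and a median of -0.73 (camera adjusted p = 0.000146; adjusted p = 0.906 with an estimated correlation). Without G007-LK replicate 1 the median was -0.10 and the list was not called. Nuf2 and the low-signal Chek2 fell, and 3 members fell adjusted over the list alone; Kif23 and Kif20a were low. Markers of epithelium (median -0.59 over 10 genes), T and NK cells (-0.45 over 38) and B cells (-0.03 over 8) gave camera adjusted p values of 0.425, 0.205 and 0.999. Their medians were -0.07, 0.52 and 0.67 without G007-LK replicate 1.

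With the replicate number as a block limma called 63 genes, 41 higher and 22 lower, among them all 27, while quantile normalization gave 15 higher and 14 lower and the fixed reference list 14 and 13. Median-ratio rescaling gave 14 calls (13 of the 27), a common background floor 7 (Car9, Ccnd1, Cd14, Cd68, Gpnmb, Ms4a4a and Tyrobp), and omission of control replicate 2, control replicate 3 or G007-LK replicate 1 gave 16 each (16, 16 and 15 of the 27), against 47 without G007-LK replicate 2; without G007-LK replicate 1 the myeloid list alone was still called.

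**Figure D3:**
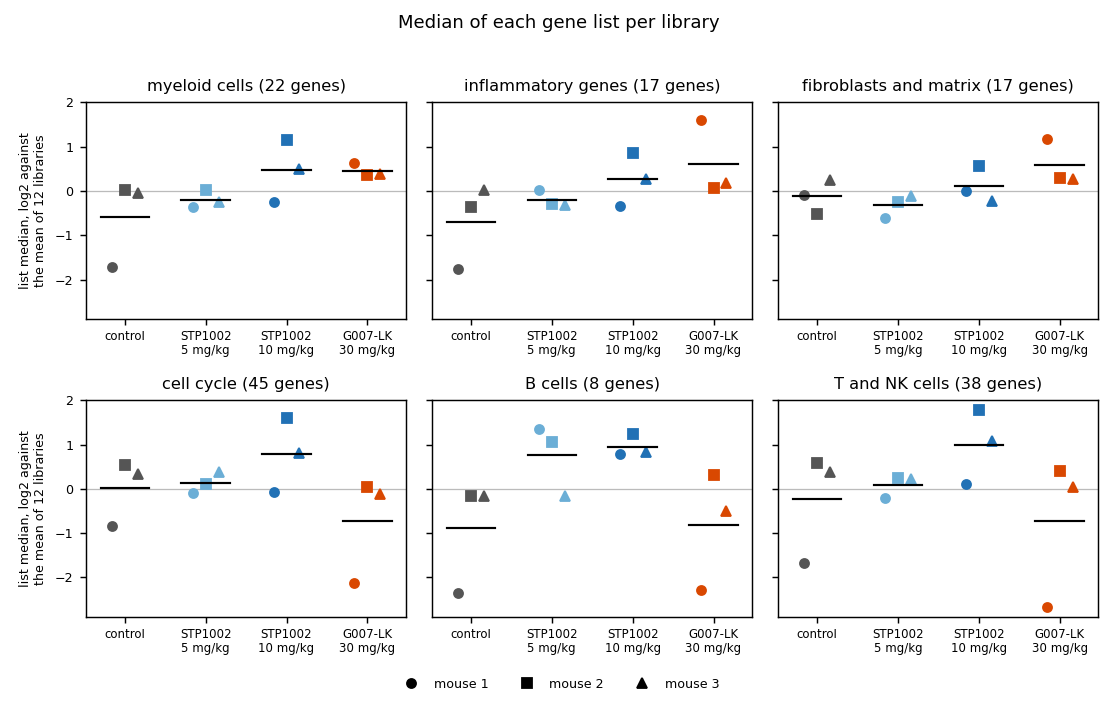
Median of 6 gene lists in each library, as log2 against the mean of the 12 libraries, 1 point per mouse (n = 3 per group) and lines at the group means. The B cell list lies at -2.35 in control replicate 1 and at 1.36 in STP1002 5 mg/kg replicate 1.

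In mice given STP1002 at 10 mg/kg no single gene was called against control mice. The list of B cell markers was higher at camera's preset correlation (camera adjusted p = 0.0123) and was not called with an estimated one (adjusted p = 0.771 with an estimated correlation). Cd22, an inhibitory receptor of B cells, averaged 63.2 ± 27.7 (SD, n = 3) in control mice and 410.2 ± 151.6 (SD, n = 3) after treatment, a log2 fold change of 2.72 ± 0.81 SE. H2-Ob, which modulates peptide loading on MHC class II, averaged 73.9 ± 37.4 and 434.0 ± 127.4 (log2 fold change 2.66 ± 0.75 SE). The transcription factor Spib had 1.84 ± 0.70, the phagocyte oxidase subunit Ncf1 1.81 ± 0.58, and the leukocyte phosphatase Ptpn6 1.65 ± 0.53. Each of these 5 genes was higher in 3 of 3 treated mice than in any control mouse, at a limma adjusted p of 0.464, the smallest of the comparison. Chek2 and the B cell kinase Blk had low signal.

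Limma called 0 of 780 genes for STP1002 at 10 mg/kg, with 36 at an unadjusted p under 0.05. The counts by edgeR and DESeq2 were 0 as well, with 45 and 60 genes at an unadjusted p under 0.05. Groups did not overlap for 95 genes (12.2%), where chance gives 10%. The median log2 fold change of all genes was 0.69 on the deposited scale and 0.01 after median-ratio rescaling, so the values above include a shift of the whole panel. The core genes Ccnd1 (-1.11 ± 0.66 SE) and Cd44 (-0.02 ± 0.91) were not called, with limma adjusted p of 0.464 and 0.993. Neither were Ctnnb1 (-0.17 ± 0.49; limma adjusted p = 0.825), nor Myc (0.57 ± 0.47) and Mki67 (0.10 ± 0.89), which turned to -0.13 and -0.58 after median-ratio rescaling.

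Camera called 2 of 26 lists at this dose. All 8 B cell markers were higher, with a median of 1.65 on the deposited scale and 0.97 after median-ratio rescaling (camera adjusted p = 0.0123; adjusted p = 0.771 with an estimated correlation). None of them was called over all genes and 3 were adjusted over the list alone. Myeloid markers were higher in all 22 members, with a median of 1.04, or 0.35 after median-ratio rescaling (camera adjusted p = 0.0164; adjusted p = 0.771 with an estimated correlation). The list had 0 members called by limma, over all genes or adjusted over the list alone, and the neutrophil gene Csf3r (1.41 ± 0.69 SE) and Cd68 (1.10 ± 0.56) were among those with the smallest p. The median of the B cell list, centred over the 12 libraries, was -2.35 in control replicate 1 and -2.28 in G007-LK replicate 1, and between -0.49 and 1.36 in the other libraries. With the replicate block 4 lists were called, T and NK cell markers (higher) and glycolysis (lower) in addition, and without STP1002 10 mg/kg replicate 1 the count was 0. It was 4 without replicate 2 of that dose and without replicate 2 or 3 of 5 mg/kg, and 5 without control replicate 2. A fit of the 2 groups alone called Cd22 and H2-Ob, array weights called 283 genes, omission of the 2 deepest libraries gave 5, and a common background floor left 0 lists.

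At 5 mg/kg of STP1002, again no single gene was called against control mice. Ptpn6 had a log2 fold change of 1.88 ± 0.53 SE, from 48.1 ± 20.3 (SD, n = 3) to 179.8 ± 73.0 (SD, n = 3). The MHC class II genes H2-Eb1 and H2-Aa, which present antigen, had 1.65 ± 0.53 and 1.77 ± 0.59, and these 3 genes were higher in 3 of 3 treated mice than in any control mouse. Limma adjusted p was 0.998 for each. Limma called 0 of 780 genes, with 18 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0, with 25 and 26. Array weights gave 17 calls and omission of the 2 deepest libraries 3. Groups did not overlap for 37 genes (4.74%), where chance gives 10%. Of the core genes, Ccnd1 had -0.30 ± 0.66, Cd44 0.90 ± 0.91, Ctnnb1 0.06 ± 0.49 (-0.07 after median-ratio rescaling), Myc -0.06 ± 0.47 and Mki67 -0.49 ± 0.89.

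Camera called 4 lists at 5 mg/kg. B cell markers were higher in all 8 members, with a median of 1.27 (camera adjusted p = 2.26e-08; adjusted p = 0.376 with an estimated correlation), and 2 members were called adjusted over the list alone. This rests on 2 of 3 mice. The median of the list, centred over the 12 libraries, was 1.36 and 1.06 in replicates 1 and 2 of this dose and -0.16 in replicate 3, level with -0.17 and -0.16 in control replicates 2 and 3. Cd22 stood at 55.8 in replicate 3, within the range of the control mice (31.7 to 83.5). Antigen presentation genes, which include MHC class I and class II, were higher in 13 of 16 members, with a median of 0.17 (camera adjusted p = 0.00256; adjusted p = 0.376 with an estimated correlation). H2-Eb1, H2-Aa, H2-Ab1 (1.77 ± 0.64 SE) and H2-Ob (1.97 ± 0.75) had the smallest p of that list, and 0 members were called by limma adjusted over the list alone. In replicate 3 of this dose H2-Ab1 (171.1) and H2-Ob (89.3) lay within the range of the control mice (113.2 to 223.2 and 30.83 to 96.99). Fibroblast and matrix genes were lower, 4 of 17 members being higher, with a median of -0.30 (camera adjusted p = 0.00267; adjusted p = 0.647 with an estimated correlation). Fbn1 had -0.57 ± 0.44 SE and the laminin chain Lamb1 -0.49 ± 0.46, while Lama2 and Hgf were low. Amino acid and one-carbon metabolism was lower, with a median of -0.28 over 7 genes (camera adjusted p = 0.0118; adjusted p = 0.317 with an estimated correlation). Glutamine synthetase (Glul) had -1.01 ± 0.51 SE and the glutamine transporter Slc1a5 -0.67 ± 0.41; neither list had a member called adjusted over the list alone. Without control replicate 1 the count of lists was 2, without control replicate 3 it was 1, and without STP1002 5 mg/kg replicate 3 it was 7.

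Taking both STP1002 doses against control (6 mice against 3), MHC class II and other leukocyte genes were among those with the smallest p. Log2 fold changes were 1.77 ± 0.46 SE for Ptpn6, 1.63 ± 0.46 for H2-Eb1, 2.32 ± 0.65 for H2-Ob and 1.75 ± 0.50 for Ncf1, at a limma adjusted p of 0.408 each. Limma called 0 of 780 genes, with 30 at an unadjusted p under 0.05. Counts by edgeR and DESeq2 were 0, with 37 and 46 at an unadjusted p under 0.05, while array weights gave 32 and omission of the 2 deepest libraries 7. The median of all genes was 0.39, and -0.01 after median-ratio rescaling. Core genes were not called; Ccnd1 had -0.70 ± 0.57, Ctnnb1 -0.05 ± 0.43, Cd44 0.44 ± 0.79 and Mki67 -0.19 ± 0.77, while Myc had 0.25 ± 0.41 and -0.16 after median-ratio rescaling.

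For both doses camera called 5 lists, 3 higher and 2 lower. The B cell list was higher in all 8 members, with a median of 1.44 (camera adjusted p = 8.25e-06; adjusted p = 0.418 with an estimated correlation) and 4 members called adjusted over the list alone; Cd22 had 2.41 ± 0.70 SE. Antigen presentation was higher in 14 of 16 members, with a median of 0.64 (camera adjusted p = 0.0123; adjusted p = 0.418 with an estimated correlation) and 3 members called adjusted over the list alone; H2-Aa had 1.52 ± 0.51 SE. Myeloid markers were higher in 21 of 22 members, with a median of 0.74 (camera adjusted p = 0.00953; adjusted p = 0.546 with an estimated correlation). Their member Cd84 had 2.10 ± 0.98 SE, and the list had 0 members called by limma adjusted over the list alone. Fibroblast and matrix genes were lower in the test, with 8 of 17 members higher and a median of -0.10 (camera adjusted p = 0.0123; adjusted p = 0.499 with an estimated correlation). Fbn1 had -0.59 ± 0.38 SE, the collagens Col6a1 -0.47 ± 0.36 and Col4a2 -0.58 ± 0.49, and the growth factor Fgf7 0.81 ± 0.58. Glycolysis genes had a median of -0.20 over 10 genes, or 0.01 after quantile normalization (camera adjusted p = 0.0242; adjusted p = 0.418 with an estimated correlation). Hexokinase Hk2 had -1.25 ± 0.77 SE, the regulator Pfkfb3 -0.59 ± 0.46, the glucose transporter Slc2a1 0.58 ± 0.41 and the isomerase Tpi1 0.62 ± 0.57. Neither of the lower lists had a member called adjusted over the list alone. Without control replicate 1 the count of lists was 2, and without STP1002 10 mg/kg replicate 3 it was 3.

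**Figure D4:**
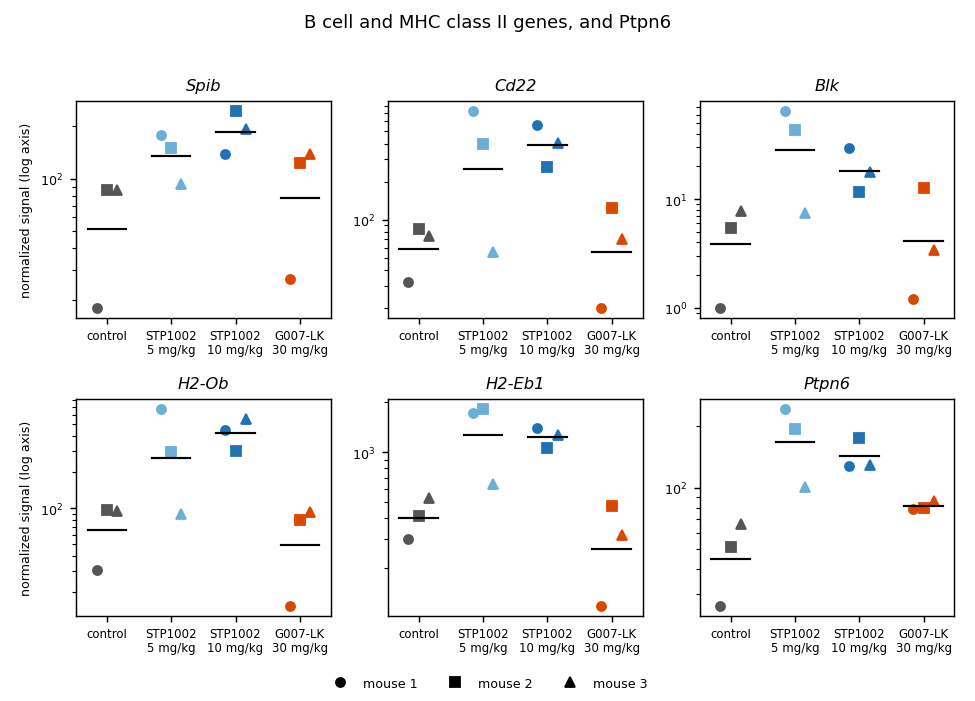
Normalized signal (log axis) of B cell and MHC class II genes in the 4 groups, 1 point per mouse (n = 3 per group) and lines at the back-transformed group means of the log2 values. Cd22 has arithmetic means of 63.2 in control mice, 392.5 and 410.2 with STP1002 at 5 and 10 mg/kg, and 70.8 with G007-LK.

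Between the doses of STP1002, the gene with the smallest p was Itga1, a collagen-binding integrin subunit, at 202.1 ± 54.3 (SD, n = 3) with 5 mg/kg and 65.2 ± 58.3 (SD, n = 3) with 10 mg/kg. Its log2 fold change was -1.97 ± 0.69 SE. The chemerin receptor Cmklr1 had 1.39 ± 0.49, the smooth muscle actin Actg2 -1.54 ± 0.60 and the macrophage scavenger receptor Cd163 1.32 ± 0.54; Brca1 was low. Limma adjusted p was 0.654 for each, and the 3 mice of each dose did not overlap. Limma called 0 of 780 genes, with 18 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0, with 15 and 18; array weights gave 388 calls. Groups did not overlap for 83 genes (10.6%), where chance gives 10%. Camera called 0 of 26 lists, with 2 at an unadjusted p under 0.05, and fry called 0. The median of all genes was 0.56 on the deposited scale and 0.01 after median-ratio rescaling. The 95% interval of the log2 difference ran from -3.44 to -0.51 for Itga1 and from 0.19 to 2.46 for Cd163, without adjustment for the number of genes.

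G007-LK was also set against STP1002 directly. Gpnmb was above background in 0 of 3 libraries of STP1002 at 10 mg/kg and was at least 30.7-fold higher with G007-LK (limma adjusted p = 0.000342). Log2 fold changes were 4.73 ± 0.81 SE for Ms4a4a, 4.49 ± 0.74 for Slpi, 3.58 ± 0.91 for Cd44 and 3.74 ± 0.89 for Ptgs2, the inducible cyclooxygenase, with limma adjusted p from 0.00491 for Slpi to 0.0366 for Cd44. H2-Ob had a log2 fold change of -3.08 ± 0.75 SE, Car9 -3.43 ± 0.63, Sfn -3.34 ± 0.77 and Ccnd1 -3.21 ± 0.66, with limma adjusted p from 0.00967 for Car9 to 0.0311 for H2-Ob.

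Limma called 24 of 780 genes in this comparison, 16 higher and 8 lower, and in all 24 the groups did not overlap. The unadjusted p was under 0.05 for 194 genes, and 173 genes (22.2%) did not overlap, where chance gives 10%. The median of all genes was -0.74, or -0.03 after median-ratio rescaling and -0.97 on the fixed reference list, and the split became 15 higher and 1 lower with that scaling and 14 and 14 on the fixed reference list. With the replicate block 260 genes were called, 51 higher and 209 lower, among them all 24. Of the 18 genes higher and 9 lower against control, 12 and 3 were also called here, where independent lists would share 0.369 and 0.0923; both comparisons use the same G007-LK mice. A common background floor left 2 calls, Gpnmb and Ms4a4a, and omission of 1 mouse gave 5, 10 and 3 calls for STP1002 replicates 1, 2 and 3, and 9 and 53 for G007-LK replicates 1 and 2.

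Camera called 7 lists between G007-LK and STP1002 at 10 mg/kg. Fibroblast and matrix genes were higher in 11 of 17 members, with a median of 0.32 (camera adjusted p = 0.000511; adjusted p = 0.534 with an estimated correlation). Col4a1 (2.63 ± 0.53 SE) and Fbn1 (2.03 ± 0.44) rose, and 4 members did adjusted over the list alone. TGF-beta and BMP genes were higher in 9 of 13 members, with a median of 0.51 (camera adjusted p = 0.0126; adjusted p = 0.251 with an estimated correlation). Of these Thbs1 rose (2.98 ± 0.61 SE), also as the 1 member called adjusted over the list alone. Cell cycle genes were lower, with 3 of 45 members higher and a median of -1.38 (camera adjusted p = 0.0126; adjusted p = 0.837 with an estimated correlation). T and NK cell markers were lower, with 1 of 38 members higher and a median of -1.70 (camera adjusted p = 0.0126; adjusted p = 0.837 with an estimated correlation). Without G007-LK replicate 1 the medians were -0.66 and -0.69 for the cell cycle and the T and NK list, and neither was called. Neither of these lower lists had a member called by limma, over all genes or adjusted over the list alone. The 14 genes of other organs, the germ line and pluripotent cells, partly chosen after values were seen, were lower as well. Their medians were 38.2, 164.0 and 90.0 in STP1002 10 mg/kg replicates 1 to 3, and 3.78, 53.7 and 45.1 in G007-LK replicates 1 to 3. A lower T and NK list thus need not mean fewer such cells. Cyclin B1 (Ccnb1) had -3.09 ± 0.99 SE and the T cell co-receptor Cd8a -3.02 ± 1.05. In G007-LK replicate 1 Cd8a lay at the floor of 1, which stands for 3 counts or fewer, and in replicate 2 it had 12 counts. Both lie below the background thresholds of 14.4 and 15.8 counts, and the fold change of Cd8a includes the floored value.

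The myeloid list had a median of 0.02, and -0.21 on the fixed reference list, and was higher in camera's test against the other genes (camera adjusted p = 0.0486; adjusted p = 0.837 with an estimated correlation). Its members Cd14 (3.25 ± 0.73 SE), Cd68 (2.41 ± 0.56) and Tyrobp (2.00 ± 0.44) rose and the chemokine receptor Ccr2 (-2.72 ± 0.63) fell; adjusted over the list alone 4 rose and 1 fell. Inflammatory genes differed in sign between median and test: the median was -0.09, and 0.64 after median-ratio rescaling, while the test was upward (camera adjusted p = 0.0265; adjusted p = 0.837 with an estimated correlation). Ptgs2 was the 1 member called, also adjusted over the list alone. The panel reference genes had a median of 0.19, and -0.05 after rescaling on these same genes, with 0 of 15 members called by limma over all genes or adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.251 with an estimated correlation). The deposited scale holds the geometric mean of the 20 inferred reference genes nearly constant, while the median of all genes was -0.74 in this comparison. The call of the panel reference list may thus come from the scaling. Without G007-LK replicate 1, the fibroblast list was the 1 list called.

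Set against STP1002 at 5 mg/kg, Gpnmb had a log2 fold change of 5.64 ± 0.70 SE, Cd14 3.88 ± 0.73, Ms4a4a 3.90 ± 0.81, Thbs1 3.37 ± 0.61 and Ptgs2 3.50 ± 0.89, all higher with G007-LK. Lower with G007-LK were Ccnd1 (-4.02 ± 0.66 SE), Car9 (-3.98 ± 0.63) and Sfn (-3.76 ± 0.77), and Nuf2 was at least 2.57-fold lower. Limma adjusted p for these 9 genes ran from 0.000311 for Gpnmb to 0.0461 for Nuf2. Limma called 22 of 780 genes, 14 higher and 8 lower, none with overlapping groups, and 99 had an unadjusted p under 0.05. Groups did not overlap for 156 genes (20.0%), where chance gives 10%. The median of all genes was -0.23, or -0.08 after median-ratio rescaling and -0.43 on the fixed reference list. Calls shared with the comparison against control numbered 11 higher and 5 lower, where independent lists would share 0.323 and 0.0923. Both comparisons use the same G007-LK mice, so the lists are not independent. The split became 9 higher and 10 lower with quantile normalization and 11 and 13 on the fixed reference list. Median-ratio rescaling left 6 calls, a common background floor 10, a fit of the 2 groups alone 1 (Gpnmb), and omission of STP1002 5 mg/kg replicate 1 or G007-LK replicate 1 left 7 each. Other alternatives raised the count, to 33 without G007-LK replicate 2 and to 61 with the replicate block, although these pairs did not pass the pairing rule.

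Camera called 7 lists between G007-LK and STP1002 at 5 mg/kg. Fibroblast and matrix genes were higher in 15 of 17 members, with a median of 0.93 (camera adjusted p = 1.26e-05; adjusted p = 0.434 with an estimated correlation). Fbn1 (1.98 ± 0.44 SE) and Col4a1 (2.33 ± 0.53) rose, and 6 members did adjusted over the list alone. Myeloid markers were higher in 14 of 22 members, with a median of 0.62 (camera adjusted p = 0.00217; adjusted p = 0.865 with an estimated correlation); Cd68 (3.09 ± 0.56 SE), Cd14 and Tyrobp (2.26 ± 0.44) rose, and 5 rose and 1 fell adjusted over the list alone. Inflammatory genes were higher in 10 of 17 members, with a median of 0.63 (camera adjusted p = 0.00963; adjusted p = 0.865 with an estimated correlation); Ptgs2 and Lcn2 (2.78 ± 0.71 SE) rose, and 4 members did adjusted over the list alone. TGF-beta and BMP genes had a median of 0.54 over 13 genes (camera adjusted p = 0.0112; adjusted p = 0.329 with an estimated correlation), with Thbs1 called both ways.

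Cell cycle genes had a median of -0.76 over 45 genes (camera adjusted p = 0.00217; adjusted p = 0.944 with an estimated correlation); Nuf2 fell, and 0 members did adjusted over the list alone by limma. B cell markers were lower in all 8 members, with a median of -1.11 (camera adjusted p = 0.0112; adjusted p = 0.865 with an estimated correlation). None was called over all genes and 3 were adjusted over the list alone, and Cd22 had -2.16 ± 0.81 SE. T and NK cell markers had a median of -0.80 over 38 genes (camera adjusted p = 0.0265; adjusted p = 0.944 with an estimated correlation), and 0 members were called by limma adjusted over the list alone; the granzyme Gzma had -1.74 ± 0.75 SE. Without G007-LK replicate 1 the myeloid and fibroblast lists alone were called, and the medians were -0.11 for the cell cycle list, -0.54 for the B cell list and 0.18 for the T and NK list. The 14 genes of other organs, the germ line and pluripotent cells had medians of 3.78, 53.7 and 45.1 in G007-LK replicates 1 to 3. They were 29.6, 41.7 and 50.2 in replicates 1 to 3 of STP1002 at 5 mg/kg.

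Any difference among the 4 groups was called by limma's moderated F test for 21 of 780 genes, led by Gpnmb (adjusted p = 0.000178), Car9 (adjusted p = 0.0030) and Ccnd1 (adjusted p = 0.00443). With the replicate block the count was 110, although the pairs with STP1002 at 5 mg/kg did not pass the pairing rule. A common background floor left 1 gene. Counts without single mice were 9 for STP1002 5 mg/kg replicate 1 and STP1002 10 mg/kg replicate 3, 11 or 12 for STP1002 10 mg/kg replicates 1 and 2, G007-LK replicate 1 and control replicate 2, 13 for control replicate 3, and between 15 and 29 for the other 5.

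Whether both compounds move the same genes was examined through their fold changes against the same 3 control mice. Across 780 genes, which are not independent replicates, the covariance of the log2 fold changes of G007-LK and STP1002 at 10 mg/kg was 0.106, and Pearson's r was 0.133. Unchanged groups simulated against shared controls gave a mean covariance of 0.274 (95th percentile 0.317) and a mean r of 0.5001. The observed covariance minus the simulated mean was -0.168. With gene-to-gene correlation kept in the simulation its mean was 0.249 and its 95th percentile 0.877, and the simulated covariance was as large as the observed one in a share of 0.611. These simulations take equally numbered libraries as independent, although the numbers of these 3 groups passed the pairing rule. With the spread of the fit with the replicate block, the simulated mean was 0.135 (95th percentile 0.162) and the difference -0.0286. With gene-to-gene correlation in addition, the mean was 0.131, the 95th percentile 0.442 and the share 0.463. The difference between observed and simulated covariance thus depends on the pairing. No gene was called in both comparisons by limma, as 27 and 0 genes were called, and the difference between the compounds was tested directly above. The 3 control mice were not split between the fold changes, as 1 part would hold a single mouse. Part or all of the observed covariance may thus come from the shared controls. Each simulated mean for unchanged groups (0.274, 0.249, 0.135 and 0.131) lay above the observed 0.106.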

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

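The edgeR and DESeq2 tests, the background alternatives, the omission of 2 or 3 libraries together, the rescaling on bright reference genes and the simulations of shared fold changes with gene-to-gene correlation or the replicate block were chosen only after the values had been seen; the other alternatives were fixed at the outset. Of the counts of called genes and lists and the shared fold changes, 394 values stayed within 1.5 times the reported count or within the spread, and 119 moved further. Of the named genes, 5114 values kept their direction and side of the threshold, 335 lost a call, 173 gained one and 78 turned sign. Each turned value belonged to a gene that was not called in the comparison concerned. Where a value moved, the cause was not tested, unless fewer genes, fewer mice or another threshold made the alternative. Genes at the common floor in all libraries give no value. All alternatives fixed at the outset were run, and leaving out 1 mouse kept at least 2 in each group.

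Depth sets the limit. Signals under the background threshold of a library cannot be told from probe background there; it was highest in G007-LK replicate 2 (40.4 normalized units), 29.3 in the shallowest library, control replicate 3, and lowest in control replicate 1 (4.33). Sign turned in the core genes Ctnnb1, Myc, Mki67, Cd44 and Ccnd1 and in Gpt, Csf3r and Tpi1. For Cd44 and Ccnd1 it turned only in comparisons of STP1002 with control.

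Scale and filters. With log2(value + 10), the fold change of Mki67 was 0.13 for G007-LK and that of Cd44 0.012 for STP1002 at 10 mg/kg. Without genes of a mean under 20, 4 lists were called for STP1002 at 10 mg/kg. With genes of a mean under 100 left out the lists numbered 3 for G007-LK and 4 for STP1002 at 10 mg/kg against control, and 1 each for G007-LK against 10 and against 5 mg/kg.

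Median-ratio rescaling called 14 genes for G007-LK against control, 6 against STP1002 at 5 mg/kg and 11 for any difference among the 4 groups. Fold changes under it were 0.019 for Mki67 with G007-LK, -0.13 for Myc and -0.58 for Mki67 with 10 mg/kg, -0.069 for Ctnnb1 with 5 mg/kg and -0.16 for Myc with both doses. Rescaling on the fixed reference list gave -0.11 for Ctnnb1 with G007-LK and -0.0026 for the log2 fold change of Myc, G007-LK vs control, and -0.0097 for Ctnnb1 with 5 mg/kg. Quantile normalization called 3 lists for G007-LK and 6 for 10 mg/kg. It gave -0.067 for Ctnnb1 with G007-LK, -0.13 for Myc and -0.54 for Mki67 with 10 mg/kg, and -0.15 for Myc with both doses. Rescaling on the reference genes above background in all libraries called 4 lists for 10 mg/kg, with 0.085 for Mki67 with G007-LK, -0.27 for Mki67 with 10 mg/kg and -0.039 for Ctnnb1 with 5 mg/kg.

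For eBayes without trend the genes called were 4 for G007-LK against 10 mg/kg, 13 against 5 mg/kg and 11 for any difference. Array weights called 160 genes for G007-LK, 283 for 10 mg/kg, 17 for 5 mg/kg and 32 for both doses against control. They called 388 between the doses, 491 and 126 for G007-LK against 10 and 5 mg/kg, and 625 for any difference. Lists called with array weights were 2 for G007-LK, 2 for 5 mg/kg, 3 for both doses, and 1 and 3 for G007-LK against 10 and 5 mg/kg. Fold changes were -0.086 for Ctnnb1 with G007-LK, 0.45 for Cd44 with 10 mg/kg and 0.078 for Gpt with 5 mg/kg.

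Fits of only the groups compared called 15 genes for G007-LK, 2 for 10 mg/kg (Cd22 and H2-Ob) and 1 for G007-LK against 5 mg/kg (Gpnmb), and 7 lists for 10 mg/kg. With the replicate number as a block 63 genes were called for G007-LK against control, 260 against 10 mg/kg, 61 against 5 mg/kg and 110 for any difference, and 4 lists for 10 mg/kg. For the shared fold changes, the observed covariance of 0.106 minus the simulated mean was -0.168 without the block and -0.0286 with it. The block moved no other count of genes or lists beyond 1.5 times, and the pairs with 5 mg/kg did not pass the pairing rule. An adjusted p under 0.1 gave 38 genes for G007-LK against 10 mg/kg and 32 for any difference, and 8 lists each for 10 mg/kg and for both doses.

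Camera with an estimated correlation called 0 lists for G007-LK, 10 mg/kg, 5 mg/kg and both doses against control, and 0 for G007-LK against 10 and against 5 mg/kg. Fry called 2 lists for G007-LK against control and 2 against 10 mg/kg, and 0 for 10 mg/kg, 5 mg/kg, both doses and G007-LK against 5 mg/kg.

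On the recovered counts, edgeR with TMM called 12 genes for G007-LK against 5 mg/kg and 34 for any difference. Its fold changes were 1.49 for Mki67 with G007-LK, -0.096 for Myc and -0.70 for Mki67 with 10 mg/kg, -0.19 for Ctnnb1 with 5 mg/kg, and -0.29 for Cd44 and -0.093 for Myc with both doses. EdgeR without normalization factors gave 0.80 and -0.20 for Mki67 with G007-LK and 10 mg/kg. DESeq2 called 47 genes for G007-LK, 68 against 10 mg/kg, 59 against 5 mg/kg and 64 for any difference. Fold changes by DESeq2 were 1.52 for Mki67 with G007-LK, -0.15 for Myc and -0.74 for Mki67 with 10 mg/kg, -0.26 for Ctnnb1 with 5 mg/kg and -0.15 for Myc with both doses.

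Subtraction of the background left 1 list for 10 mg/kg, with -0.00070 for the log2 fold change of Ctnnb1, STP1002 5 mg/kg vs control. A common background floor left 7 genes for G007-LK, 2 against 10 mg/kg, 10 against 5 mg/kg and 1 for any difference. Lists under that floor numbered 2 for G007-LK, 0 for 10 mg/kg, and 1 and 3 for G007-LK against 10 and 5 mg/kg, and Mki67 had 0.69 with G007-LK and 0.019 with both doses. Restriction to genes above background in at least 9 libraries gave 16 genes for G007-LK, 5 lists for 10 mg/kg and 4 for G007-LK against 10 mg/kg.

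Without the 2 deepest libraries, 5 genes were called for 10 mg/kg (among them Cd22, H2-Ob, Plcb3 and Ptprc) and 3 for 5 mg/kg (Dock2, H2-Ab1 and Ptprc), named after their values were seen. The counts were 7 for both doses, 38 and 34 for G007-LK against 10 and 5 mg/kg, and 39 for any difference. Lists came to 2 for 5 mg/kg, 2 for both doses, and 1 and 3 for G007-LK against 10 and 5 mg/kg. Fold changes were -0.042 for Ctnnb1 with G007-LK, 0.038 for Ctnnb1 and 0.56 for Cd44 with 10 mg/kg, 0.28 for Ccnd1 and 0.17 for Gpt with 5 mg/kg, and 0.15 for Ctnnb1 with both doses. Without the 3 libraries farthest out on the first component the genes called were 4 for 10 mg/kg (among them Cd22, H2-Ob and Ptprc), 8 for both doses, 34 for G007-LK against 5 mg/kg and 38 for any difference. The lists were 2 for 5 mg/kg, 2 for both doses, and 2 and 3 for G007-LK against 10 and 5 mg/kg. Fold changes were -0.042 for Ctnnb1 with G007-LK, 1.16 for Cd44 and -0.097 for Mki67 with 10 mg/kg, and 0.28 for Ccnd1 and 0.17 for Gpt with 5 mg/kg. With both doses they were 0.0028 for Ctnnb1, -0.065 for Myc, 0.016 for Ccnd1, -0.15 for Csf3r and -0.11 for Tpi1.

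Leaving out each mouse in turn gave between 16 and 47 genes for G007-LK against control, 3 and 53 against 10 mg/kg, 7 and 33 against 5 mg/kg and 9 and 29 for any difference. Lists ranged from 1 to 6 for G007-LK, 0 to 5 for 10 mg/kg, 1 to 7 for 5 mg/kg, 2 to 6 for both doses, and 1 to 8 and 2 to 7 for G007-LK against 10 and 5 mg/kg. With G007-LK, Mki67 ranged from -1.26 to 0.62 and Ctnnb1 from -0.25 to 0.39. At 10 mg/kg, Ctnnb1 ranged from -0.46 to 0.073, Cd44 from -0.61 to 0.58 and Mki67 from -0.14 to 0.29. At 5 mg/kg, the ranges were -0.78 to 0.39 for Ccnd1, -0.78 to 0.17 for Gpt, -0.094 to 0.36 for Ctnnb1 and -0.27 to 0.059 for Myc. With both doses Ctnnb1 ranged from -0.20 to 0.15. The counts of genes for 10 mg/kg, 5 mg/kg, both doses and between the doses were 0 without any single mouse.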

Other observations

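The tests of the myeloid, B cell and dim-gene patterns below were chosen only after the results were seen, and so were the genes named here outside the fixed rule; the regroupings of the libraries were planned. In the hypoxia list, G007-LK moved the transcription factor Hif1a and its target Car9 in opposite directions. Hif1a rose from a mean signal of 118.5 to 1118 (log2 fold change 2.45 ± 0.65 SE, limma adjusted p = 0.0459), while Car9 fell. Replicate 1, the deepest library, weighs most in the treated mean of Hif1a, with 8977 recovered counts against 105 and 438 in G007-LK replicates 2 and 3. The hypoxia list had a median of -0.0094 over 8 genes (camera adjusted p = 0.999). Cd274, the checkpoint ligand PD-L1 and a member of the interferon list, rose by 2.70 ± 0.65 (limma adjusted p = 0.0276). The other 16 members of that list were not called, and 8 of 17 were higher (camera adjusted p = 0.792). The complement receptor C3ar1 rose by 2.46 ± 0.51 and the secreted follistatin-like protein Fstl1 by 2.19 ± 0.47, both at a limma adjusted p of 0.0109. All 4 genes were higher in 3 of 3 treated mice than in any control mouse.

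Wnt target genes had 5 measured members, of which Ccnd1 fell and Cd44 rose with G007-LK, so that the list had a median of -0.28 (camera adjusted p = 0.792). Over the 15 tested lists that were called in no comparison, camera adjusted p ranged from 0.157 (DNA repair) to 0.999 for G007-LK against control. For STP1002 it ranged from 0.0611 (TCA cycle and oxidative phosphorylation) to 0.883 at 10 mg/kg, and from 0.164 (epithelial markers) to 0.976 at 5 mg/kg.

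Myeloid markers were called higher with G007-LK than in control mice by camera at its preset correlation, with 5 of 22 members called by limma (adjusted p = 0.833 for the list with an estimated correlation). The 2 deepest libraries do not account for all of it, since 5 members were called without control replicate 1 and G007-LK replicate 1, although the list median was then 0.21. Background counts in the shallow libraries do not account for all of it either, as 3 members (Cd14, Cd68 and Tyrobp) were still called with values under the highest threshold set to it. A lower share of epithelium in the G007-LK pieces may contribute. The myeloid median exceeded that of other non-epithelial markers by 0.694 (95% interval -0.266 to 1.94, 15 against 31 members with a mean of at least 100). That restriction was set after the value over all members, 1.12 (0.368 to 1.71), was seen. Both intervals come from a bootstrap over genes with the mice held fixed, so they leave out the spread between mice. Over all members the median was 0.65 for fibroblast and matrix genes and -0.03 for B cell markers. It was -0.45 for T and NK cells, -0.24 for endothelium, -0.52 for smooth muscle (2 genes) and -0.59 for mast cells and eosinophils. A lower share of epithelium alone would raise all of these. The B cell and the T and NK medians did turn positive without G007-LK replicate 1, so the test cannot decide. Repeated injection, dose and schedule differ together with the compound, so an effect of the route stays open, untested, beside one of G007-LK.

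B cell markers were called higher with both doses of STP1002 than in control mice by camera at its preset correlation, with 0 of 8 members called by limma over all genes (adjusted p = 0.418 for the list with an estimated correlation). Control replicate 1 alone does not account for this, as the median for both doses was 0.82 without it and 1.44 with it. The list median of STP1002 5 mg/kg replicate 3 (-0.16) was level with those of control replicates 2 and 3 (-0.17 and -0.16). Uneven amounts of lymphoid tissue in the pieces are a candidate explanation that the test cannot decide. Within groups the members rose and fell together, with a mean residual correlation of 0.701. This lay at percentile 99.8 of 10000 random gene sets of like expression (median 0.102, 95th percentile 0.437). The random sets were not matched on cell type, and any cause that moves B cell markers together gives such a value. Control replicate 1 and G007-LK replicate 1 were low in the B cell list (-2.35 and -2.28) and in the T and NK list (-1.66 and -2.66). The 14 genes of other organs, the germ line and pluripotent cells, partly chosen after values were seen, were lowest there too. Their medians were 13.4 and 3.78 in these libraries, against 29.6 to 164.0 in the others. The low lymphoid medians thus do not point to lymphoid tissue in particular. The labels do not say whether Peyer's patches were removed. A change in B cells under STP1002 was not tested apart from this.

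Dim genes were lower in the 2 deepest libraries on the deposited scale, and so was the median of all genes. The 100 dimmest genes outside the immune and cell cycle lists had medians of 7.93 in control replicate 1 and 8.31 in G007-LK replicate 1. In the other libraries these lay between 9.59 and 15. The median of all genes was 40.5 and 41.9 in these 2 libraries and between 65.6 and 203.4 in the others. Probe background that does not scale with the amount of RNA may add to this. The intervals that follow come from a bootstrap over genes with the libraries held fixed, so they leave out the spread between mice. The counts of the 100 dimmest genes rose with the reference genes at a median slope of 0.890 (95% interval 0.644 to 1.08) against 0.977 for the 100 brightest. These dim genes had means up to 67.1, so the slope does not cover mid-level genes. The bound written against probe background, a median slope above 0.8, was met, but the interval reaches below it. The bound and its comparison with the interval were set after 0.890 was seen. For 14 genes of other organs, the germ line and pluripotent cells the slope was 0.0814 (-0.0539 to 0.176), but 8 of them had been seen with flat counts before the list was written, so that the value decides nothing (6 unseen genes: 0.181). A lower share of immune cells in these libraries could give the same picture, and equally dim immune genes differed in slope by -0.110 (-0.669 to 0.502, 21 genes). None of these can be told apart with 12 libraries.

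Called genes and lists were also counted after regrouping the libraries. With 3 against 3 mice there are 10 splits, too few for a share under 0.05. For genes, the real split and the highest other gave 27 and 1 for G007-LK against control (1 split as large), 24 and 0 against STP1002 at 10 mg/kg (1 split) and 22 and 0 against 5 mg/kg (1 split). They gave 0 and 0 for 10 mg/kg against control, 5 mg/kg against control and between the doses (10 splits each, as every split reaches a count of 0). For lists the values were 5 and 6 for G007-LK (5 splits as large), 2 and 5 for 10 mg/kg (8 splits), 4 and 7 for 5 mg/kg (5 splits) and 0 and 5 between the doses (10 splits). Against G007-LK they were 7 and 8 for 10 mg/kg (3 splits) and 7 and 6 for 5 mg/kg (1 split). Among the 4 splits that part all 3 equally numbered pairs, the highest other count was 0 genes for G007-LK against control and against 10 mg/kg, unblocked or blocked, where the real blocked counts were 63 and 260.

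Larger designs were regrouped by 100 random draws, the real one included. For both doses against control, 100 of 100 gave at least the real 0 genes (highest other 4), which tests nothing, as every draw reaches 0. At least the real 5 lists were called in 12 of 100 (highest other 8), so chance is not excluded for the lists. Any difference among the 4 groups gave 21 genes against 17 in the highest other draw, 1 of 100 as large, the real one included. This share holds only for draws that ignore the replicate numbers. In 100 draws that exchanged mice only within a number, added later, 2 were as large, the real one included, with 21 genes against 23 in the highest other draw, and with the replicate block 2 were as large, with 110 against 142. Other groupings of these mice can thus give as many calls, although in a share under 0.05. The draws for both doses and for the covariance also ignore the numbers. The covariance of the fold changes of both compounds, 0.106, was reached in 77 of 100 draws, with 1.498 as the highest other.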
